A study of Homo sapiens with 15 samples.

How the data were processed

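RNA was measured by sequencing in 15 libraries of Caco-2 cells, a human colorectal adenocarcinoma line that forms enterocyte-like monolayers. The labels gave 5 libraries of untreated control cells, 5 of cells exposed to polysorbate 20 (PS20) and 5 of cells exposed to polysorbate 80 (PS80). Per the labels, each emulsifier was given at 0.05% for 24 h. Total RNA was isolated with a column kit and libraries were made from polyadenylated RNA, per the labels' protocols.

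Each deposited table held whole-number read counts per gene for 1 library, without normalization. Per the file headers, the authors counted with featureCounts, version 2.0.0 in 11 libraries and version 2.0.3 in PS80 replicates 1, 3, 4 and 5. An effect of that separate counting cannot be told apart from one of PS80 in those 4 libraries, which limits both PS80 comparisons. Per the file headers, the annotation was GENCODE release 42 in the version with patches, haplotypes and scaffolds, with a mapping quality minimum of 10 and no option for strand or for read pairs. Trimming with cutadapt, alignment with STAR 2.7.9a and testing with DESeq2 1.32.0 against GRCh38 were taken from the submitters' processing notes. The tables listed 69215 genes, of which 62672 (90.55%) were paired with a gene symbol through the gene name table supplied with the reference. At most 0.00174% of a library's counts lay on identifiers without a symbol.

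This processing limits several measurements. Counting without strand does not separate a gene from an antisense partner, and reads in exons shared by overlapping genes were left unassigned by default. The share of exonic bases that also lay in an exon of another gene was 47.8% for TAGLN, 39.6% for DDIT3, 27.2% for NGFR, 25.4% for ICAM1 and 22.2% for ACAT2. Histone genes, ribosomal protein genes and AKR1C2 have near-identical copies, so their counts are uncertain. The 6519 genes annotated on scaffolds and patches had 0 counts in all 15 libraries. In chromosome 6 from 29 to 33 Mb, the region of the major histocompatibility complex, 119 of 153 protein-coding genes (77.8%) also had 0 counts, against 15 of 154 (9.74%) in the neighbouring 25 to 29 Mb and 34 to 38 Mb. The low counts of TJP1 (mean 2.03 CPM, the counts scaled to library size) and OCLN (9.67 CPM), which share 27 of 30 and 13 of 18 distinct exon lengths with an annotated copy on a scaffold, were therefore not read as expression levels.

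Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and in Python 3.11.15. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12769 genes. Trimmed mean of M-values factors lay between 0.978 and 1.02, and the common biological coefficient of variation was 8.91%. Groups were compared by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in a model with 1 term per group over all 15 libraries, at an adjusted p threshold of 0.05. Log2 CPM for components, lists and the separation of groups used a prior count of 2, and fold changes used edgeR's default. Errors of log2 fold changes are standard errors, and intervals are at the 95% level. Levels are CPM with SD over the 5 libraries of a group. Total counts per library ranged from 4183096 to 42271053, a ratio of 10.1, with a median of 8829612.

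The groups, the tests, the alternatives, 38 gene lists and the rule for naming genes were fixed before the data were examined. Of the lists, 36 had at least 5 tested genes. They were compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01 and, as alternatives, by camera with an estimated correlation and by fry. The directional p of fry tests whether a list's genes move, on balance, in 1 direction, and its mixed p tests whether they change in either direction. Neither compares the list with other genes. The rule named, for each comparison, the 8 highest and 8 lowest log2 fold changes among genes that passed, had a mean of at least 5 CPM and separated the groups completely, leaving out clone-based names, small and antisense RNAs and pseudogenes. It added the 3 members with the smallest p of each list that was called, in the list's direction, and up to 4 members that passed, in either direction, of 5 lists on junctions, inflammation, apoptosis and cholesterol synthesis. Some genes that the rule named are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

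Replicate numbers in the sample titles were shared between groups, so it was checked whether libraries with the same number deviated together from their group means. For PS80 and control all 5 correlations across genes were over 0.1 (0.102 to 0.304), and the numbers were taken as possible pairs there. PS80 replicates 1 and 5 correlated better with a control of another number (0.171 against 0.139, and 0.215 against 0.125). Mean correlations between groups were 0.153 within replicates 1 and 2 and 0.0952 within replicates 3 to 5. Pairs therefore cannot be told from that split, and the main test used no block. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries of the same group held the same counts within sampling noise (chi-square per degree of freedom 1.69 to 40.3). Pairs across groups were not compared in this way.

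The alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter, a filter of 1 CPM in 5 libraries, only the groups compared, the replicate number as a block, split controls and leaving out each library in turn. A term for replicates 1 and 2 against 3 to 5, fits to either part alone, and that term with an estimated correlation were added after seeing the data. The fits were tested on simulated counts with 50 changed genes for each size of change. For PS20 against control, changes of 1.5-fold, 2-fold and 4-fold were recovered for 69.4%, 91.7% and 100% of genes (12457 genes in the fit). The shares were 70.8%, 90.0% and 100% for PS80 against control (12472 genes) and 73.5%, 94.0% and 98.0% for PS80 against PS20 (12497 genes). False calls made up 3.45%, 8.11% and 9.19% of calls in these comparisons.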

Results

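The data compared the transcriptomes of Caco-2 monolayers under 2 food emulsifiers and without treatment. PS20 and PS80 are related nonionic surfactants, polyoxyethylene sorbitan esters that differ in their fatty acid part, which is laurate in PS20 and oleate in PS80. Each group held 5 libraries, and both exposures were at 0.05% for 24 h. Total counts per library were 4183096 to 13616301 in control (median 7291913), 6749086 to 17251564 with PS20 (median 8335083) and 6769409 to 42271053 with PS80 (median 10120136). Mitochondrially encoded RNA made up 1.497% to 1.914% of counts in control, 2.03% to 2.58% with PS20 and 1.45% to 2.97% with PS80. The first principal component (39.0% of variance) placed control between -31.5 and -24.7, PS20 between 21.9 and 33.4 and PS80 between -4.30 and 10.01. The second component (13.7%) placed PS80 between -26.8 and -12.2 and the other libraries between 2.07 and 13.8.

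Samples also differed in ways that the groups did not explain. In every group, replicates 1 and 2 lay apart from replicates 3 to 5. PS80 replicate 2, the most deeply sequenced library, stood apart in histone mRNAs, whose mean level was 5.07 log2 CPM against at most 1.21 in the other PS80 libraries. Markers of fibroblasts, endothelium and blood cells were tested for 8 genes, of which 1 was higher and 2 were lower with PS20 and 2 were higher and 2 were lower with PS80 (3 and 2 adjusted over the list alone). Neither comparison called this list by limma's camera (adjusted p = 0.603 with PS20 and 0.925 with PS80), fry's directional test passed with PS20 (5.52e-05) and not with PS80 (0.639), and its median, mean and test differed in sign in both (0.02, -0.17 and down with PS20; -0.03, 0.02 and down with PS80). Between PS80 and PS20, 1 of the 8 genes was higher with PS80 and 0 were lower (median 0.18, mean 0.19). Camera did not call the list there (adjusted p = 0.343), and fry's directional test passed (2.99e-04).

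**Figure D1:**
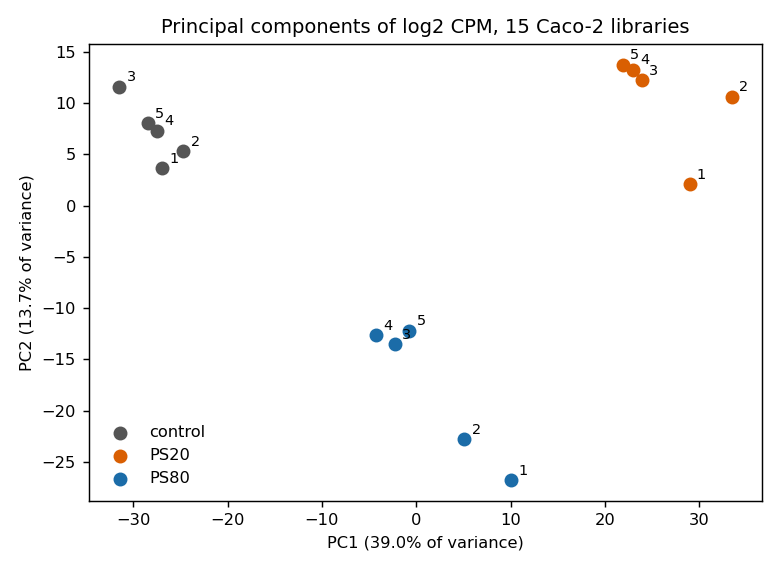
Principal components 1 and 2 of log2 CPM for the 15 libraries, each point 1 library with its replicate number and coloured by group. PS20 and control lie at opposite ends of component 1 (39.0% of variance), and PS80 lies below both on component 2 (13.7%).

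The comparison of PS20 with control asked how this emulsifier changed gene expression in an epithelial monolayer. Cells exposed to PS20 had higher mRNA of 23 of 29 genes of the integrated stress response, 22 of 26 cholesterol synthesis genes and 64 of 71 ribosomal protein genes, and lower mRNA of 33 of 46 genes of the cell cycle and DNA replication. Limma's camera called these lists, and each had adjusted p = 0.278 with an estimated correlation. ALDH1L2, a mitochondrial folate enzyme, rose 5.54-fold, from 4.28 ± 0.881 to 24.0 ± 3.97 CPM (mean ± SD, n = 5), and SLC7A11, the cystine transporter, rose 5.09-fold, from 22.3 ± 4.38 to 112 ± 20.9 CPM (n = 5). CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor, rose 9.74-fold, from 9.76 ± 1.23 to 97.1 ± 45.6 CPM (n = 5). SI, the sucrase-isomaltase of the brush border, was 7.11-fold lower, at 2.91 ± 0.819 CPM against 20.5 ± 9.47 CPM (n = 5). In the genome build GRCh38, CYP1A1 (ENSG00000140465.15) spans chromosome 15 from 74719542 to 74725536, SI (ENSG00000090402.8) chromosome 3 from 164978898 to 165078496, SLC7A11 (ENSG00000151012.13) chromosome 4 from 138164097 to 138242349, and ALDH1L2 (ENSG00000136010.14) chromosome 12 from 105019784 to 105107643.

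Of 12769 genes tested, 6150 passed, 3099 higher and 3051 lower with PS20, and 674 of these differed by more than 2-fold (432 higher, 242 lower). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change was 3.28 ± 0.32 (SE) for CYP1A1 (adjusted p = 3.29e-06), 2.47 ± 0.15 for ALDH1L2 (2.86e-12), 2.35 ± 0.16 for SLC7A11 (1.27e-08) and -2.83 ± 0.31 for SI (2.98e-06). NGFR, the low-affinity neurotrophin receptor, had the highest log2 fold change of the genes the rule named, 5.95 ± 0.44, from 0.208 ± 0.220 to 13.2 ± 3.98 CPM, and 27.2% of its exonic bases also belong to another gene. S100P, COL6A2 and KIF21B rose by 3.10, 2.30 and 2.19 on the log2 scale. CEACAM5 rose by 3.08 with a wide spread, from 1.69 ± 1.24 to 13.5 ± 11.3 CPM, and its mean over all groups was 11.7 CPM in replicates 1 and 2 and 3.71 CPM in replicates 3 to 5. Among the lowest of the genes the rule named were LCT, the lactase of the brush border (-2.35), CYP4X1 (-2.62), TM4SF4 (-2.35), NEB (-2.26) and LAMA1, a laminin chain (-2.19). The histone genes H2AC6 and H2BC5 fell by 2.21 and 2.14, and leaving out control replicate 2 ended the call of H2BC5 (adjusted p = 0.0537 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With replicates 1 and 2 alone both calls were lost (0.275 and 0.351), and without a filter that of H2BC5 (0.0618). Fits to replicates 1 and 2 alone and to replicates 3 to 5 alone called 3297 and 6331 genes.

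Of the 36 lists tested, limma's camera called 7 higher and 2 lower with PS20. Where a count adjusted over the list alone is not given beside a list, here and in the other comparisons, it was the same as the count over all genes. Among 29 genes of the integrated stress response and its transcription factor ATF4, 23 rose and 0 fell (25 and 0 adjusted over the list alone), with a median log2 fold change of 0.91 (camera adjusted p = 4.05e-12, and adjusted p = 0.278 with an estimated correlation). Its members ALDH1L2, STC2 (1.10) and PSAT1, a serine synthesis enzyme (1.04), had the smallest p. Of 71 cytosolic ribosomal protein genes, 64 rose and 0 fell (64 and 0 adjusted over the list alone, median 0.36; adjusted p = 1.15e-17, and 0.278 as the adjusted p with an estimated correlation). RPL10A rose by 0.57 and RPL9 by 0.52. Of 46 genes of the cell cycle and DNA replication, 33 fell and 0 rose, with a median of -0.29 (adjusted p = 1.11e-08, and adjusted p = 0.278 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, fell by 0.63 on the log2 scale, from 354 ± 24.8 to 230 ± 11.6 CPM, and KIF20A by 0.68. SI and LCT belong to a list of 33 enterocyte brush border genes of which 11 rose and 10 fell, and camera did not call it (adjusted p = 0.975).

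Of 31 genes of phospholipid and sphingolipid synthesis 6 rose and 13 fell with PS20 (6 and 14 adjusted over the list alone, median -0.13), which camera did not call (adjusted p = 0.201) and fry's directional test did (adjusted p = 6.99e-06). In the list of cholesterol biosynthesis and SREBP2 targets 22 of 26 genes rose and 2 fell (23 and 2 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 1.78e-06, and adjusted p = 0.278 with an estimated correlation). ACAT2, which makes the acetoacetyl-CoA that enters this pathway, rose from 180 ± 7.97 to 308 ± 30.7 CPM (log2 fold change 0.77), MVD by 0.89, SQLE by 0.50 and DHCR7 by 0.56. Among 17 genes of fatty acid synthesis 12 rose and 2 fell, with a median of 0.27, and ELOVL5, ELOVL6 and ME1 rose by 0.96, 0.81 and 0.46. That call (adjusted p = 0.0385, and adjusted p = 0.556 with an estimated correlation) ended without control replicate 4 (adjusted p = 0.0638), control replicate 5 (0.0577) or PS20 replicate 1 (0.0698).

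Among other stress genes, 18 of 30 members of the unfolded protein response rose and 1 fell (median 0.25; camera adjusted p = 2.34e-04, and adjusted p = 0.278 with an estimated correlation), with PDIA4 at 0.54, HYOU1 at 0.65 and CANX at 0.42. In the NRF2 oxidative stress list 16 of 27 genes rose and 2 fell (17 and 2 adjusted over the list alone, median 0.28; adjusted p = 9.01e-04, and adjusted p = 0.278 with an estimated correlation). Its members FTL, a ferritin chain, and AKR1C2 rose 1.56-fold and 2.37-fold. Of 32 immediate early and MAPK feedback genes 18 rose and 4 fell (median 0.36; adjusted p = 0.0126, and adjusted p = 0.278 with an estimated correlation), with KLF10 2.01-fold higher. The transcription factor MYC rose by 1.18. Nuclear genes of oxidative phosphorylation were called lower, with 19 of 46 falling and 3 rising (median -0.10; adjusted p = 0.0126, and adjusted p = 0.556 with an estimated correlation). ATP5MC1 fell by 0.54 and UQCRC1 by 0.43. With replicates 1 and 2 alone, the calls of the immediate early list (median 0.27, adjusted p = 0.0605) and the oxidative phosphorylation list (-0.12, 0.0625) were lost.

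Junction and apoptosis genes changed in both directions with PS20, and most of the inflammatory genes that passed rose. Among 34 tight junction genes 5 rose and 9 fell, and camera did not call the list (adjusted p = 0.463). AMOT, an angiomotin, fell from 178 ± 7.74 to 99.1 ± 4.08 CPM (log2 fold change -0.84 ± 0.06), and CGN, cingulin, fell from 331 ± 11.9 to 222 ± 8.11 CPM (-0.58 ± 0.05). PARD3 rose by 0.34, and MAGI2 rose by 2.38 from a low level. Of 22 adherens junction and desmosome genes 3 rose and 10 fell (adjusted p = 0.154 by camera), where PKP2, a plakophilin, fell by 0.72 and the desmoglein DSG2 rose by 0.62. Among 16 inflammatory genes 7 rose and 1 fell (median 0.35), which camera did not call (adjusted p = 0.205). ICAM1 rose by 0.82 and NFKB1 fell by 0.76. Of 29 apoptosis genes 7 rose and 7 fell (adjusted p = 0.628), with PMAIP1 and TNFRSF10B higher by 1.63 and 0.63. Fry's directional test, which does not compare a list with other genes, passed for all 4 lists (adjusted p = 0.00274, 2.06e-05, 7.20e-04 and 0.00183, in this order).

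**Figure D2:**
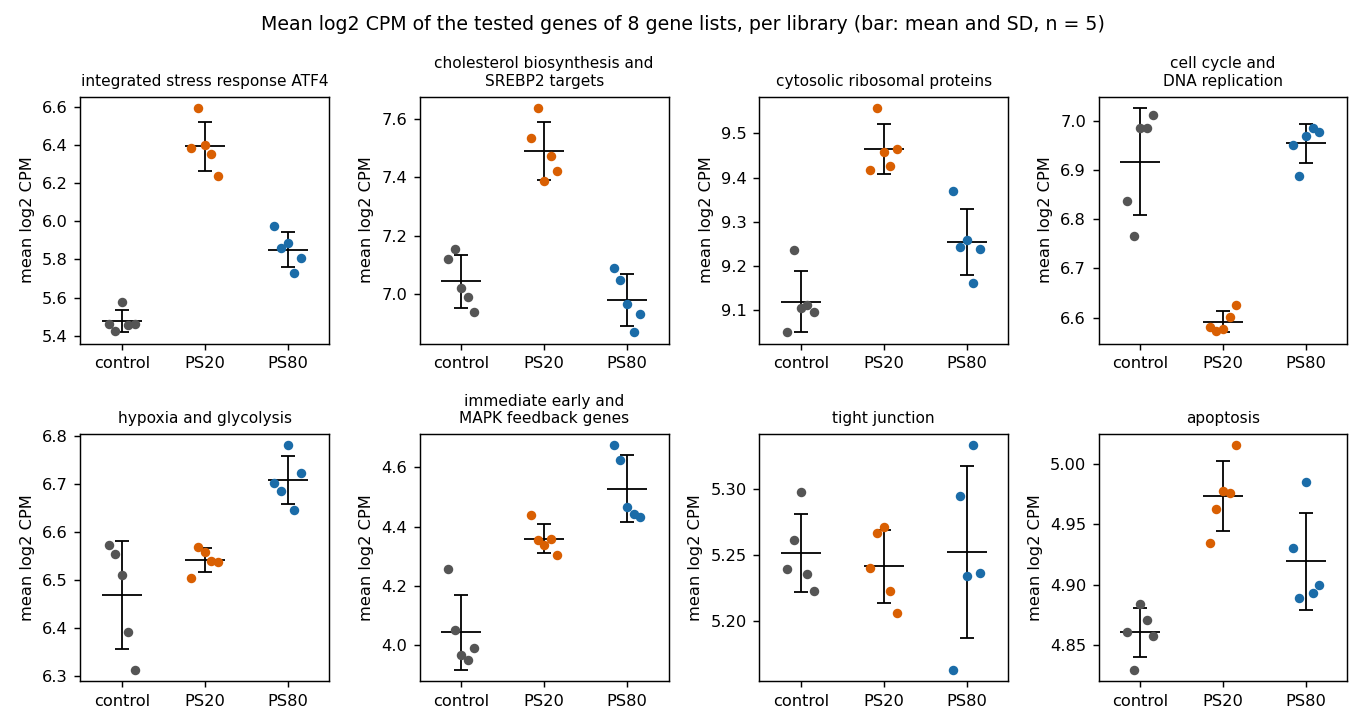
Mean log2 CPM of the tested genes of 8 gene lists in each library, with points for the 5 libraries of control, PS20 and PS80 and bars for the mean and SD. The integrated stress response list had a median log2 fold change of 0.91 with PS20 and 0.37 with PS80, and the cholesterol list one of 0.42 with PS20 and -0.04 with PS80.

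The comparison of PS80 with control asked the same of the second emulsifier. Cells exposed to PS80 had higher mRNA of 18 of 32 immediate early and MAPK feedback genes (camera adjusted p = 2.60e-06, and adjusted p = 0.185 with an estimated correlation), of the glucose transporter SLC2A1 and of the aryl hydrocarbon receptor target CYP1A1, and lower mRNA of SI and TXNIP. CYP1A1 rose 9.58-fold, from 9.76 ± 1.23 to 94.7 ± 16.4 CPM (n = 5). SLC2A1, also known as GLUT1, rose 2.16-fold, from 373 ± 22.6 to 804 ± 97.9 CPM (n = 5), and the transcription factor MYC rose 2.48-fold, from 51.6 ± 11.2 to 127 ± 21.3 CPM (n = 5). TXNIP, an inhibitor of glucose uptake, was 3.11-fold lower, at 13.9 ± 2.78 against 43.6 ± 6.50 CPM (n = 5). SLC2A1 (ENSG00000117394.24) lies on chromosome 1 from 42925353 to 42958893 and TXNIP (ENSG00000265972.6) on chromosome 1 from 145992435 to 145996579 (GRCh38).

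Of the 12769 genes, 4243 passed, 2199 higher and 2044 lower with PS80, and 286 differed by more than 2-fold (194 higher, 92 lower). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change was 3.26 ± 0.32 for CYP1A1 (adjusted p = 1.11e-05), 1.11 ± 0.08 for SLC2A1 (1.02e-08), -1.64 ± 0.18 for TXNIP (1.05e-05) and -2.002 ± 0.28 for SI (7.50e-05). NGFR rose by 2.99, to 1.63 ± 0.543 CPM, PLAUR, the urokinase receptor, by 1.90, COL6A2 by 1.64, PTPRS by 1.61, SLC16A3, a lactate transporter, by 1.60, and B4GALNT4, HIP1 and KIF21B by 1.57 to 1.58. The lowest log2 fold changes of the genes the rule named were, after SI, those of TXNIP, MYBPH (-1.62), NEB (-1.52), FAM13B (-1.42), SLC2A2, the glucose transporter GLUT2 (-1.36), PLXNC1 (-1.30) and BFSP1 (-1.27). CEACAM5 did not pass (log2 fold change 1.92). Fits to replicates 1 and 2 alone and to replicates 3 to 5 alone called 2213 and 4021 genes, and in the former NGFR, MYBPH and CYP1B1 were among the genes that no longer passed.

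All 9 lists that limma's camera called with PS80 were higher. Of 32 immediate early and MAPK feedback genes 18 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.48 (adjusted p = 2.60e-06, and adjusted p = 0.185 with an estimated correlation). Besides MYC, KLF6 rose by 0.57 and ETV5 by 1.22. In the hypoxia and glycolysis list 15 of 31 genes rose and 1 fell (16 and 1 adjusted over the list alone, median 0.18; adjusted p = 0.00221, and adjusted p = 0.409 with an estimated correlation), where PFKP, a phosphofructokinase, rose by 0.75 and SLC16A3 and SLC2A1 as given. This call was lost with replicates 1 and 2 alone (median 0.12, adjusted p = 0.4995). Of 29 integrated stress response genes 17 rose and 2 fell (19 and 2 adjusted over the list alone, median 0.37; adjusted p = 4.71e-06, and adjusted p = 0.409 with an estimated correlation). ALDH1L2 rose by 1.39, PSAT1 by 0.69 and the arginine transporter SLC7A1 by 0.63. Of 71 ribosomal protein genes 36 rose and 0 fell (43 and 0 adjusted over the list alone, median 0.15; adjusted p = 2.23e-06, and adjusted p = 0.746 with an estimated correlation), with RPL26 and RPL14 at 0.31 and 0.21. Of 20 heat shock genes 9 rose and 0 fell (median 0.14; adjusted p = 0.00346, and adjusted p = 0.571 with an estimated correlation), among them the chaperones FKBP4 (0.79), HSPB1 (0.66) and HSPA4L (0.69). The list of squamous and wound keratinocyte markers had 6 of 11 genes higher and 2 lower (median 0.36; adjusted p = 0.00924, and adjusted p = 0.223 with an estimated correlation). The members with the smallest p were PLAUR and the growth factors AREG (0.73) and EREG (0.92), which bind the epidermal growth factor receptor. This call was lost with replicates 3 to 5 alone (median 0.29, adjusted p = 0.0921).

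The other 3 calls each ended when certain single libraries were left out and in a fit to part of the replicates, with replicates 1 and 2 alone for NRF2 genes (adjusted p = 0.158) and aryl hydrocarbon receptor targets (0.0516) and with replicates 3 to 5 alone for inflammatory genes (0.0921). Of 27 NRF2 genes 14 rose and 4 fell (median 0.14; camera adjusted p = 0.0350, and adjusted p = 0.523 with an estimated correlation), with SLC7A11 at 0.93 and GSR at 0.25, and the call ended without control replicate 1 (adjusted p = 0.0999), PS80 replicate 3 (0.0636) or PS80 replicate 5 (0.0506). Of 7 aryl hydrocarbon receptor targets 4 rose and 0 fell (median 0.16; adjusted p = 0.0350, and adjusted p = 0.223 with an estimated correlation), CYP1A1, CYP1B1 (1.06) and SLC7A5 (0.45) among them, and the call ended without PS80 replicate 5 (0.0506). Of 16 inflammatory and NF-kB genes 8 rose and 1 fell (median 0.21; adjusted p = 0.0395, and adjusted p = 0.223 with an estimated correlation). NOS2, the inducible nitric oxide synthase, rose from 33.8 ± 3.09 to 68.5 ± 6.35 CPM, ICAM1 by 0.56 and TNFAIP2 by 0.86 on the log2 scale, and NFKB1 fell by 0.52. This call ended without control replicate 1 (adjusted p = 0.0535), control replicate 3 (0.0534) or PS80 replicate 5 (0.0506), and with the replicate number as a block (adjusted p = 0.0667).

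Cholesterol synthesis was not called with PS80: of 26 genes 1 rose and 5 fell (0 and 4 adjusted over the list alone, median -0.04; camera adjusted p = 0.336). IDI1, MVK and PMVK fell by 0.28, 0.29 and 0.22, and leaving out control replicate 4 ended the call of PMVK (adjusted p = 0.0528 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among 34 tight junction genes 5 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.832, with a median and mean of 0.00 and a test direction of down). AMOT fell to 116 ± 10.2 CPM (log2 fold change -0.61), CGN by 0.43 and MAGI3 by 0.51, and CGNL1 rose by 0.57. Of 22 adherens junction and desmosome genes 5 rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.871), with DSG2 at 0.61, VCL, vinculin, at 0.27, PKP3 at 0.26 and PERP at -0.31. Of 29 apoptosis genes 6 rose and 7 fell (7 and 7 adjusted over the list alone; adjusted p = 0.922). PMAIP1 and TNFRSF10B rose by 1.32 and 0.38, and BIRC2 and CASP9 fell by 0.29 and 0.50.

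**Figure D3:**
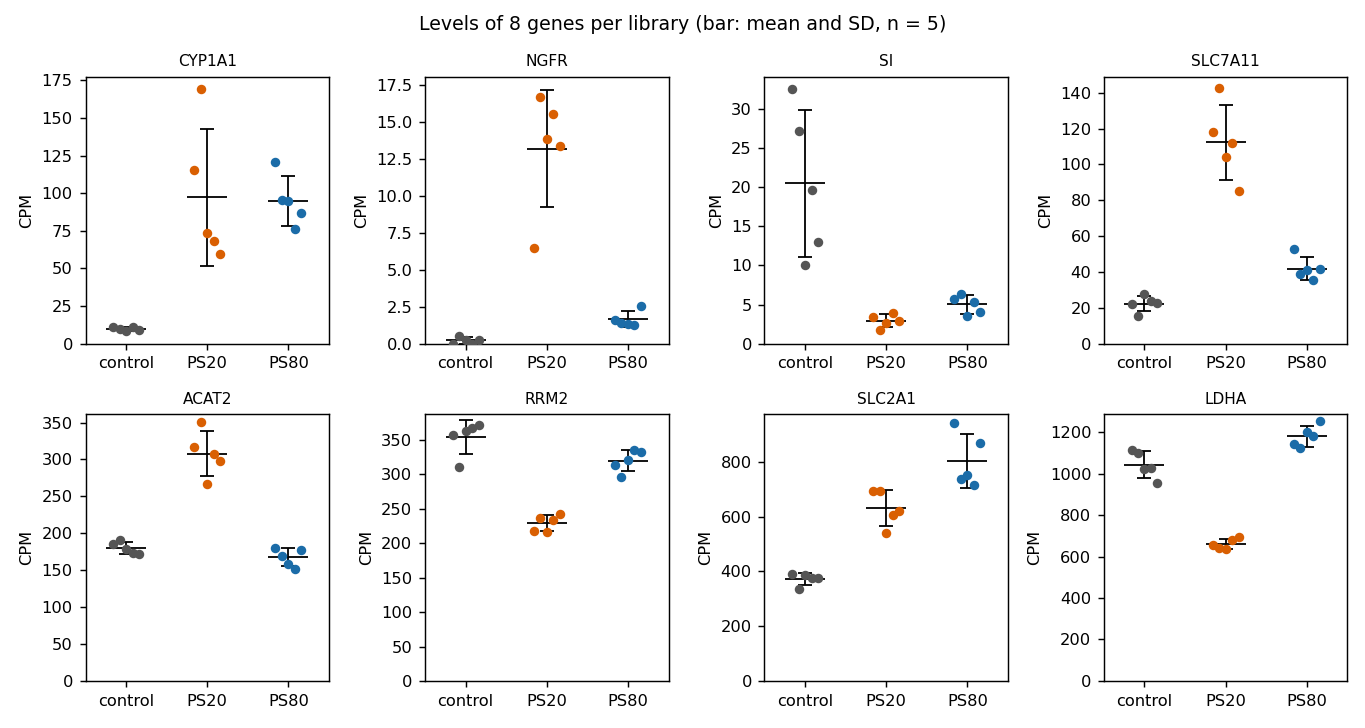
CPM of 8 genes in each library, with points for the 5 libraries of control, PS20 and PS80 and bars for the mean and SD on linear axes that start at 0. ACAT2 reached 308 CPM with PS20 and 167 CPM with PS80 against 180 CPM in control, and LDHA was at 661 CPM with PS20 and 1181 CPM with PS80.

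The direct comparison of PS80 with PS20 tested where the laurate and the oleate ester differed at the same dose and time. The glycolysis enzymes LDHA, PKM and PFKP and 39 of 46 genes of the cell cycle and DNA replication were higher, and 24 of 26 cholesterol synthesis, 20 of 29 integrated stress response and 20 of 30 unfolded protein response genes were lower, with PS80 than with PS20. Limma's camera called these 4 lists, and each had adjusted p = 0.175 with an estimated correlation. Against control, camera did not call the cell cycle list with PS80 (adjusted p = 0.759). There 13 genes rose and 9 fell (13 and 10 adjusted over the list alone, median 0.03). Nor did it call the unfolded protein response against control (5 rose and 5 fell, median -0.03, adjusted p = 0.775). Fatty acid synthesis (median -0.12, 0.583) and nuclear oxidative phosphorylation (0.01, 0.922) were also not called with PS80 against control. LDHA, a lactate dehydrogenase subunit, was at 1181 ± 51.5 CPM with PS80 and 661 ± 24.6 CPM with PS20 (n = 5), 1.79-fold higher. PKM, pyruvate kinase, was at 1130 ± 32.9 against 653 ± 35.4 CPM and MCM6 at 381 ± 12.8 against 261 ± 15.2 CPM (n = 5). ACAT2 was 1.83-fold lower with PS80, at 167 ± 12.1 against 308 ± 30.7 CPM (n = 5). LDHA (ENSG00000134333.14) lies on chromosome 11 from 18394560 to 18408425 and ACAT2 (ENSG00000120437.9) on chromosome 6 from 159762045 to 159779112 (GRCh38).

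Between the emulsifiers 4501 of 12769 genes differed, 2301 higher and 2200 lower with PS80, and 194 by more than 2-fold (67 higher, 127 lower). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change of PS80 over PS20 was 0.84 ± 0.05 for LDHA (95% interval 0.74 to 0.94, adjusted p = 9.41e-12), -0.88 ± 0.06 for ACAT2 (-1.003 to -0.75, 2.25e-10) and -2.96 ± 0.27 for NGFR (-3.53 to -2.39, 1.49e-07). Higher with PS80 were also TM4SF4 (2.04), NPPB, the natriuretic peptide B (1.90), CYP4X1 (1.58), SLC1A3, a glutamate transporter (1.36), and TAGLN, transgelin (1.35). Lower with PS80 were S100P (-1.57), LAMP3 (-1.53), DDIT4 (-1.43), SLC7A11 (-1.42), GAS5, a non-coding host of small nucleolar RNAs (-1.35), DDIT3 (-1.34) and CYP2W1 (-1.33). The genes H2AC6 and H2BC5 were higher by 1.74 and 2.40, and by 0.66 and 1.15 without PS80 replicate 2. Leaving out PS20 replicate 1, 2, 3 or 5 ended the call of H2AC6 (adjusted p from 0.0550 to 0.0668 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With replicates 1 and 2 alone the calls of H2AC6 (0.304) and H2BC5 (0.261) were lost. Fits to replicates 1 and 2 alone and to replicates 3 to 5 alone called 1612 and 4951 genes.

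For other genes the emulsifiers were not told apart. The log2 difference of PS80 from PS20 was -0.02 for CYP1A1, with a 95% interval of -0.56 to 0.52. It was 0.13 for MYC (-0.14 to 0.41), 0.00 for KLF6 (-0.13 to 0.14), -0.01 for DSG2 (-0.12 to 0.10), -0.01 for HSPB1 (-0.17 to 0.14), -0.05 for AREG (-0.16 to 0.05) and -0.31 for PMAIP1 (-0.71 to 0.09). SI was higher with PS80 than with PS20 by 0.83 (0.11 to 1.54) and did not pass after adjustment (adjusted p = 0.0676 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Over all 12769 genes, whether they passed or not, the 95% interval lay within 1.5-fold in either direction for 9261 (72.5%). This count therefore includes genes that differed by a small amount. Of the 4501 genes that passed, 861 differed by more than 1.5-fold.

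Of the lists, limma's camera called 7 higher and 9 lower with PS80 than with PS20. Of 46 cell cycle genes 39 were higher and 0 lower (42 and 0 adjusted over the list alone, median 0.34; adjusted p = 1.82e-15, and adjusted p = 0.175 with an estimated correlation), with MCM6 at 0.54 and MCM4 at 0.58. Of 26 cholesterol genes 24 were lower and 1 higher (24 and 1 adjusted over the list alone, median -0.50; adjusted p = 1.05e-12, and adjusted p = 0.175 with an estimated correlation), with SQLE at -0.54 and DHCR7 at -0.65. Of 17 fatty acid synthesis genes 11 were lower and 1 higher (13 and 1 adjusted over the list alone, median -0.35; adjusted p = 5.53e-05, and adjusted p = 0.240 with an estimated correlation). SCD, the stearoyl-CoA desaturase that makes oleate, was at 2508 ± 292 CPM with PS80 and 4599 ± 449 CPM with PS20, and the log2 fold changes of ACSL3 and GPAM were -0.55 and -0.54. Of 29 integrated stress response genes 20 were lower and 1 higher (23 and 1 adjusted over the list alone, median -0.42; adjusted p = 6.45e-10, and adjusted p = 0.175 with an estimated correlation), with WARS1 at -0.69. Of 30 genes of the unfolded protein response 20 were lower and 0 higher (22 and 1 adjusted over the list alone, median -0.26; adjusted p = 5.47e-08, and adjusted p = 0.175 with an estimated correlation), with HYOU1 at -0.57 and SEL1L at -0.48.

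Ribosomal protein genes were lower with PS80 than with PS20 for 54 of 71 genes and higher for 0 (58 and 0 adjusted over the list alone, median -0.21; camera adjusted p = 2.05e-14, and adjusted p = 0.291 with an estimated correlation), RPS20 and RPS27 among them (-0.33 and -0.31). Nuclear genes of oxidative phosphorylation were higher for 21 of 46 and lower for 3 (22 and 3 adjusted over the list alone, median 0.12; adjusted p = 3.62e-04, and adjusted p = 0.291 with an estimated correlation), with ATP5MC1 at 0.46, ATP5MC3 at 0.39 and CYC1 at 0.42. Mitochondrially encoded mRNAs were lower for 6 of 13 and higher for 0 (9 and 0 adjusted over the list alone, median -0.44; adjusted p = 1.07e-04, and adjusted p = 0.291 with an estimated correlation), among them MT-CO2 (-0.50), MT-CO3 (-0.44) and MT-ND1 (-0.45). In the hypoxia and glycolysis list 13 of 31 genes were higher and 4 lower (13 and 5 adjusted over the list alone, median 0.20; adjusted p = 0.00120, and adjusted p = 0.256 with an estimated correlation), with PFKP at 0.85 and PKM at 0.79. NRF2 genes were lower for 12 of 27 and higher for 4 (14 and 4 adjusted over the list alone, median -0.17; adjusted p = 0.0182, and adjusted p = 0.291 with an estimated correlation), with AKR1C2 at -1.21 and FTL at -0.48. Autophagy and lysosome genes were lower for 16 of 37 and higher for 5 (17 and 5 adjusted over the list alone, median -0.11; adjusted p = 0.0269, and adjusted p = 0.291 with an estimated correlation), with CTSL at -0.56, GABARAPL1 at -0.58 and MAP1LC3B at -0.39, a call lost with replicates 1 and 2 alone (median -0.07, adjusted p = 0.262). Histone genes were higher for 8 of 16 and lower for 0 (15 and 0 adjusted over the list alone, median 2.79; adjusted p = 0.00819, and adjusted p = 0.555 with an estimated correlation), and the median was 0.36 without PS80 replicate 2 (adjusted p = 0.0385). With replicates 3 to 5 alone, which also leaves out that library, the call was lost (median 0.37, adjusted p = 0.266). In splits of the PS80 and PS20 libraries drawn at random, the real one included, camera gave this list as small a p in 84 of 100. Its median lay as far from 0 in 1 of these.

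Camera called 2 adhesion lists higher with PS80 than with PS20, and neither call held in the fits to replicates 1 and 2 alone (adjusted p = 0.154 and 0.0740) or to replicates 3 to 5 alone (0.0627 for both). Of 22 adherens junction and desmosome genes 9 were higher and 1 lower (9 and 1 adjusted over the list alone, median 0.06; camera adjusted p = 0.0226, and adjusted p = 0.175 with an estimated correlation), the median was 0.04 without PS20 replicate 4, and the call ended without PS80 replicate 4 (adjusted p = 0.0504). VCL was 1.53-fold higher and PKP2 at 504 ± 34.5 against 351 ± 27.7 CPM, and NECTIN2 was higher by 0.41 on the log2 scale. Of 21 gap junction and integrin genes 8 were higher and 1 lower (median 0.14; adjusted p = 0.0269, and adjusted p = 0.291 with an estimated correlation), with ITGA1 at 0.75, LAMA5 at 0.53 and LAMA3 at 0.51, a call that ended without PS20 replicate 5 (0.0504) or PS80 replicate 1 (median 0.09, adjusted p = 0.0750). Of 31 membrane repair and endocytosis genes 10 were higher and 3 lower (10 and 5 adjusted over the list alone, median 0.13; adjusted p = 0.0434, and adjusted p = 0.296 with an estimated correlation), with S100A10 at 0.66, MYOF at 0.48 and CAPN2 at 0.45. This call ended without PS20 replicate 1 (0.0671), PS20 replicate 4 (0.0662), PS80 replicate 3 (0.0774) or PS80 replicate 5 (0.0614), and with replicates 1 and 2 alone (0.186). Interferon response genes were lower for 6 of 18 and higher for 1 (median -0.22; adjusted p = 0.0257, and adjusted p = 0.240 with an estimated correlation), with OAS1 at -0.52, IFIT3 at -0.75 and IFIT5 at -0.55, none of which passed with replicates 1 and 2 alone (adjusted p = 0.0591, 0.108 and 0.112), and the call ended without PS20 replicate 2 (0.0603) or PS80 replicate 3 (0.0774), with replicates 1 and 2 alone (0.173) and without a filter (median -0.05, adjusted p = 0.0798).

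Tight junction, inflammatory and apoptosis lists were not called between the emulsifiers by limma's camera (adjusted p = 0.469, 0.469 and 0.494), while fry's directional test passed for each (0.0412, 0.0198 and 0.0205). Of 34 tight junction genes 8 were higher and 2 lower with PS80, with MAGI2 at -1.37 from a low level, AMOTL1 at 0.27, AMOTL2 at 0.25 and MAGI1 at 0.24. With replicates 1 and 2 alone, the calls of AMOTL2 (adjusted p = 0.0530), MAGI1 (0.138), NFKB1 (0.207) and ICAM1 (0.619) were lost. Of 16 inflammatory genes 2 were higher and 1 lower, with NOS2 at 0.66, NFKB1 at 0.24 and ICAM1 at -0.27, and the call of ICAM1 ended without PS20 replicate 2 or 5 or PS80 replicate 3, 4 or 5 (adjusted p from 0.0588 to 0.0774 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 29 apoptosis genes 3 were higher and 8 lower, with BMF at -0.59 and BAX at 0.35.

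In all 3 comparisons, 0 of these list calls held when camera estimated the correlation between genes. With the later term for replicates 1 and 2 against 3 to 5 as well, 0, 1 and 2 lists were called. These were immediate early genes with PS80, and cholesterol and fatty acid synthesis between PS80 and PS20. Other splits of the 10 libraries compared called as many lists as the real one in 6 of 100 for PS20 against control and 19 of 100 for PS80 against control, the real split included, so chance was not excluded for the number of lists called there. For PS80 against PS20 that number was 1 of 100.

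The changes with the 2 emulsifiers were also set against each other. Of the genes that passed in both comparisons with control, 2839 changed in the same direction (1434 higher, 1405 lower), where independent lists of these sizes would share 534 and 488. A total of 103 genes changed in opposite directions (3.50% of the overlap). All of these also differed between PS80 and PS20, which follows largely from the selection because the 3 contrasts share 1 model. The number was 204 (5.54%) with the replicate number as a block and 187 (5.20%) with the term for replicates 1 and 2. It was 165 (5.68%) with replicates 3 to 5 alone and 8 (0.62%) with replicates 1 and 2 alone. LDHA and VCL fell with PS20 and rose with PS80 (-0.66 and 0.18; -0.35 and 0.27), and SCD and GPAM rose with PS20 and fell with PS80 (0.47 and -0.41; 0.27 and -0.26). Of the 2839 genes, 892 differed between the emulsifiers, and the change was smaller with PS80 for 768 of them and larger for 124. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.686 (jackknife error over libraries 0.0444) and a covariance of 0.125. In 20 simulations without changes, all 15 libraries, controls included, were drawn from the control means. Each gene was drawn independently, without the split between replicates 1 and 2 and replicates 3 to 5. The mean correlation was 0.554 and the mean covariance 0.0128. At most 2 and 1 genes were called in the 2 comparisons, so the 0 shared genes found there say little. The difference of the covariances was 0.112. With the controls split so that each emulsifier had its own, the mean over 20 splits was 1421 shared genes (471 for independent lists), a correlation of 0.570 and a covariance of 0.109. Fits to replicates 1 and 2 alone and to replicates 3 to 5 alone gave 1291 and 2739 shared genes.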

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

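The tests on cells in S phase, on a batch, on reads that match 2 copies and on low expression were chosen only after the results they bear on had been seen. The tests on depth and on the selection of polyadenylated RNA were fixed before. Of 468 groups of 5 libraries tested (15 for library measures, 69 for gene lists and 384 for 128 genes), 33 had a highest or lowest library whose gap to the nearest other library, divided by the group's whole range, was above 0.71. Chance gives about 1 in 20 groups, or 23.4 here. Control replicate 1, PS20 replicates 1 and 2 and PS80 replicates 2 and 4 each held 4 of the 33.

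PS80 replicate 2 stood apart in histone mRNAs, with a gap of 0.931 of the range for the list (5.07 against 1.21 log2 CPM), 0.898 for H2BC5 and 0.830 for H2AC6 (38.2 and 24.7 CPM). Depth was argued against as the cause, since the slope on total counts within groups predicted 3.49% (error 8.04) of the excess of 4.004 log2 units. More cells in S phase were also argued against, because the cell cycle list was lower in this library (6.89 log2 CPM) than in the other PS80 libraries (6.95 to 6.99). The difference from their mean was -0.0833, and their SD was 0.0146. In control too, replicates 1 and 2 were lower for this list (6.84 and 6.77) than replicates 3 to 5 (6.98 to 7.01). The outcome set for no such excess was a level within the range of the other PS80 libraries, so PS80 replicate 2 met neither outcome. Weaker selection of polyadenylated RNA in this library is a candidate explanation, since 16 of 17 other listed RNAs without a poly(A) tail were highest of all 15 libraries in it, against 1 in the next library. The filter, at least 15 counts over all libraries, favoured this deepest library, and RNVU1-7 and RNU5B-1 had 0 counts in all others. Of RNAs with counts in every library, SNORA73B, SNORD3A and SNORD17 were at 44.7, 32.3 and 8.14 CPM here. Elsewhere they reached at most 4.56, 2.22 and 2.51 CPM. Weaker selection stays a hypothesis, no biological explanation specific to this library was given by the design, and RMRP, chosen after its values were seen, was at 857 CPM there against at most 37.5 CPM elsewhere.

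Replicates 1 and 2 lay apart from replicates 3 to 5 in all 3 groups along the direction that separates them. Depth was argued against, as log2 total counts explained 2.18% of the variance within groups along that direction, and at most 5.90% with 1 library left out. A batch that the labels do not give may be the source. The difference correlated across genes between groups with r from 0.273 to 0.446, where r over 0.3 in each pair had been set as the bound, so this cannot be told from the present values. Among genes chosen after their values were seen, AFP averaged 67.6 CPM in replicates 1 and 2 and 36.0 CPM in replicates 3 to 5, and COL3A1 9.80 and 24.1 CPM.

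Many genes with a copy on an alternate scaffold of the primary release had low or no counts. Outside the chromosome 6 region, 54.1% of 314 such protein-coding genes (95% interval 48.5% to 59.8%) had 0 counts against 16.6% of genes without a copy, a difference of 37.5 percentage points, while 45.9% had counts. For 293 genes whose copy lies on a later patch the share was 18.4%, and over all 607 genes, the set first tested, it was 36.9%. The difference is consistent with reads that match both copies not having been counted. Low expression was argued against by RPS18 and RPS9, the listed ribosomal protein genes with a copy on a scaffold of that release, whose median was 0.297 CPM against 215 CPM at the boundary of the lowest 10% and a median of 795 CPM over 70 without. RPL7A (1533 CPM) and RPS25 (742 CPM), whose copies lie on patches, were not part of that test. That bound replaced an earlier one, the lowest ribosomal protein gene without a copy, under which the result had favoured low expression, because the lowest genes without a copy, RPS10 (1.40 CPM) among them, also lay near 0. With 2 genes and a bound set after the result, this argues only weakly.

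The other libraries that stood apart are given as values. In PS20 replicate 3 the total was 17251564 counts against 8829612 in the nearest library (0.802 of the range) and 22362 genes had a count against 20100 (0.734). In PS80 replicate 2 protein-coding genes held 97.3% of counts against 98.5% (0.819). Among lists, PS20 replicate 1 was low for NRF2 genes (0.740), control replicate 3 was high for the integrated stress response (0.741) and PS80 replicate 1 was high for oxidative phosphorylation (0.785). PS20 replicate 1 was low for NGFR (0.759), LAMA1 (0.823) and MYBPH (0.725), PS20 replicate 2 was high for RPL10A (0.805), BMF (0.720) and RPL26 (0.746) and low for LAMA3 (0.836), PS20 replicate 3 was high for FKBP4 (0.785) and PS20 replicate 4 was low for PTPRS (0.803), and PS20 replicate 5 was low for KLF6 (0.902). Control replicate 1 was low for HYOU1 (0.846) and high for IDI1 (0.765), ACSL3 (0.731) and CGNL1 (0.720), control replicate 2 was low for RRM2 (0.788), SLC2A1 (0.750) and CANX (0.754), control replicate 3 was low for MT-CO3 (0.823) and control replicate 5 was low for AMOTL1 (0.728). PS80 replicate 1 was low for KIF20A (0.792), and PS80 replicate 4 was low for NOS2 (0.734), GABARAPL1 (0.832), MVK (0.724) and RPS27 (0.840).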

How the results depend on the processing

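The term for replicates 1 and 2 against 3 to 5, the fits to either part alone, and that term with an estimated correlation were chosen only after the data were seen. Of 3588 values of named genes under the alternatives, 3549 kept their direction and their side of the threshold, 39 lost significance and 0 reversed, and DESeq2 gave no adjusted p for 3. Of 714 values of called lists, 610 were kept, 104 lost significance and 0 reversed. Genes called with replicates 1 and 2 alone fell to 3297 for PS20 against control, 2213 for PS80 against control and 1612 for PS80 against PS20, with 1291 shared and a correlation of 0.637, in a fit with 6 of the 15 libraries. With replicates 3 to 5 alone they were 6331, 4021 and 4951. DESeq2 called 6109, 4216 and 4434 genes, of which 5761, 4057 and 4254 were also called by edgeR. Without a filter, 2304 genes were higher and 1611 lower with PS80 than in control. Between PS80 and PS20 they were 2474 and 1747. The higher share was thus 58.9% and 58.6% of calls, against 51.8% and 51.1% in the main fit.

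With an estimated correlation, camera called 0, 0 and 0 lists. With that and the added term it called 0, 1 and 2, which were immediate early genes with PS80, and cholesterol and fatty acid synthesis between PS80 and PS20. The estimate replaces the preset 0.01 by a value taken from the residuals of the libraries, and the cause of each list's loss was not tested further. By the directional test of fry, 24, 16 and 26 lists passed, and by its mixed test 35, 33 and 34. The histone list was lost in PS80 against PS20 with fry (adjusted p = 0.109) and with replicates 3 to 5 alone (0.266). With replicates 1 and 2 alone, the calls lost in PS80 against control were hypoxia and glycolysis (0.4995), NRF2 (0.158) and aryl hydrocarbon receptor targets (0.0516). Without a filter, the inflammatory list in PS80 against control (0.128 against a range of 0.0506 to 0.304 over the other alternatives that ended it) and the interferon list in PS80 against PS20 (0.0798) were lost.

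The correlation of the log2 fold changes of both emulsifiers was 0.614 with DESeq2 and 0.608 without a filter, where genes of low count enter. Their covariance was 0.361 and 0.671 in these settings, against 0.125 in the main fit, so its size depends on the filter. The correlation was 0.570 with split controls, which share no library and hold fewer, and 1421.25 genes were shared there. Leaving out 1 library at a time gave 5575 to 6039 genes for PS20 against control, 3557 to 4126 for PS80 against control and 3807 to 4387 for PS80 against PS20, and 8 to 11, 6 to 10 and 14 to 17 lists. The shared genes then ranged from 2337 to 2786 and the correlation from 0.663 to 0.704.

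With the replicate number as a block, 6866, 5179 and 5451 genes and 11, 8 and 16 lists were called, 3481 genes were shared and the correlation was 0.698. In PS80 against control, where the numbers may pair the libraries, the block ended the call of the inflammatory list (adjusted p = 0.0667) and changed the call of no other list or named gene. In the other comparisons the correlation of same-numbered libraries was over 0.1 in 3 of 5 pairs each (from -0.0264 to 0.248 for PS20 and control, and 0.0741 to 0.290 for PS80 and PS20), so the number was not taken as a pairing. Not every library correlated best with its own number. The block added interferon and mitochondrially encoded mRNAs to the lists called with PS20.

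Not all small changes were recovered, and what limits this was not tested. At 4183096 to 42271053 counts per library, the smallest simulated changes were recovered for 28.6% to 42.9% of genes and changes of 1.5-fold for 69.4% to 73.5%, so a gene that did not pass cannot be read as unchanged. The simulations called 174 to 185 genes, against 4243 to 6150 in the data. With fewer calls the adjustment is stricter, so these shares may understate the recovery in the data.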

Other observations

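The test on nonsense-mediated decay was written before its result was seen. The comparison of list medians over other splits, the count of splits by replicates 1 and 2 or by pairs for lists, and the genes and host gene list below, were chosen only after results had been seen.

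Several well-known junction genes lay outside the naming rule. CLDN2, the pore-forming claudin 2, rose with PS80 from 5.39 ± 1.08 to 9.42 ± 1.61 CPM (n = 5; log2 fold change 0.76, adjusted p = 5.97e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With PS20 it was at 6.87 ± 1.11 CPM and did not pass (0.29), and it was higher with PS80 than with PS20 by 0.47 (adjusted p = 0.0164 by the same edgeR test). CLDN7 rose by 0.15 with PS20 and 0.24 with PS80, and CLDN4 rose by 0.17 with PS20 and did not pass with PS80 (0.09). CDH1, E-cadherin, was at 1574 ± 49.6 CPM in control, 1706 ± 20.5 CPM with PS20 and 1585 ± 33.1 CPM with PS80, with log2 fold changes of 0.12, which passed, and 0.01, which did not. CLDN1 did not pass in either comparison with control (0.12 and 0.27).

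DDX46, an RNA helicase of the spliceosome, had the smallest p of all genes in PS20 against control. It fell by 1.34 with PS20 and by 0.47 with PS80, from 284 ± 10.9 CPM to 112 ± 4.76 and 205 ± 17.5 CPM (n = 5). The small nucleolar RNA host gene GAS5 was at 68.0 ± 11.3 CPM in control, 235 ± 21.5 CPM with PS20 and 91.8 ± 10.2 CPM with PS80. In a list of 16 other host genes 10 rose and 2 fell with PS20 (median log2 fold change 0.50), 5 rose and 1 fell with PS80 (0.14), and 1 was higher and 9 were lower with PS80 than with PS20 (-0.33). GAS5 and ZFAS1 were left out of that list because their values had been seen. A hypothesis was that transcripts removed by nonsense-mediated decay accumulated with PS20. The mRNAs of 8 decay factors that are decay targets themselves may then rise too, but 1 of 8 rose and 6 fell, with a median of -0.29, which argues against it.

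Other splits of the libraries into groups of the same sizes were drawn at random, 100 for each pair of groups with the real one included, with only the groups compared in the fit. The real split called 6076 genes for PS20 against control, 3884 for PS80 against control and 4525 for PS80 against PS20. The highest other split called 0, 0 and 1, so a chance assignment of these libraries can be excluded for these counts (1 of 100 splits each). The splits take each library as a separate sample, and the labels do not say that replicates are separate cultures. A difference between cultures is therefore not excluded, nor is one from the separate counting of most PS80 libraries. Among the 16 splits of PS80 and control that part all 5 pairs of numbers, the highest other also called 0 genes. For lists, 6 of 100 splits called as many as the real one in PS20 against control (12, highest other 14) and 19 of 100 in PS80 against control (9, highest other 14), so chance cannot be excluded there. In PS80 against control the 18 others all placed 3 or 4 of the 4 libraries of replicates 1 and 2 in the same group, which points to that structure. Among the 48 drawn splits with 2 of these libraries in each group the real one alone called as many. The 16 that part all 5 pairs also place 2 of these libraries in each group, and 2 of them called as many, the real one included (9, highest other 9). The real split was therefore not alone among all such splits, since the other one had not been drawn. These 16 are too few for a share under 0.05. For PS80 against PS20 it was 1 of 100 (16, highest other 14), so the real split alone called as many among those drawn. Not every possible split was drawn, and another split came close with 14 lists. Chance is therefore excluded only for the number of lists among the drawn splits, and not for each list called. Judged by its camera p, the real split was among fewer than 5 of 100 for 3 of 9, 3 of 9 and 7 of 16 called lists. Judged by how far the list's median lay from 0, it was so for 9 of 9, 7 of 9 and 14 of 16. By camera p these were the integrated stress response, NRF2 and ribosomal protein lists with PS20. With PS80 they were the integrated stress response, immediate early and aryl hydrocarbon receptor lists. Between PS80 and PS20 they were the cell cycle, cholesterol, integrated stress response, unfolded protein response, hypoxia and glycolysis, NRF2 and adherens junction lists.

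Regrouping all 15 libraries 100 times gave 2839 shared genes in the real grouping and at most 0 in the others (1 of 100). Regrouping mixes the treatments and so removes the effects of both emulsifiers. It therefore cannot tell whether they shared more genes than separate effects against the same controls would. The correlation of 0.686 was reached in 21 of 100 regroupings (highest other 0.835), so chance cannot be excluded for it. The covariance was 0.125 in the real grouping and at most 0.0726 in the others. The most genes called in either comparison of another regrouping was 2793. Regroupings can spread the treatments unevenly, so these calls cannot be told apart from effects of treatment.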
